A study of Drosophila melanogaster with 10 samples.

How the data were processed

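The samples were total RNA of whole adult Drosophila melanogaster females, 5 control lines and 5 lines selected for heat resistance, with 1 array per line. Groups and line numbers were taken from the sample titles. The replicates are independent lines per the series design text, so p-values measure the spread between lines. Age, mating status and treatment of the flies before sampling were not used here.

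The deposited values are probe set intensities on a linear scale, made by the authors with GCRMA (a background correction that uses probe sequence, with normalization across arrays and a summary per probe set), per the submitters' processing notes. The version and any other step are not given in the sources used here. That the scale is linear was read from the values, which are all above 0 and reach 32744. GCRMA pulls dim probe sets toward a common floor, so differences of weakly expressed genes are understated. Its normalization across arrays assumes that most transcripts do not differ. The 23 control probe sets of other organisms lay at 2.13 to 3.64 on the log2 scale, and genes near that level carry little information.

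The table holds 14010 probe sets. A platform annotation gave 1 gene for 12443 of them, several genes for 327 and none for 1240. Probe sets with several genes were not named. The gene identifier of 12393 of the single-gene probe sets was found in a RefSeq gene table of Drosophila melanogaster (assembly Release 6 plus ISO1 MT), and 0 symbols needed an update. That table was used for names, chromosome arms and the order of neighbouring genes, and no coordinates are printed since the build of the array design is not given in the sources used here.

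Values were analysed as log2(intensity + 1), so differences are on the log2(value + pseudocount) scale, which understates the change of dim genes. Features were kept when their log2 value was above 3 on at least 5 of the 10 arrays, whatever the group. The 44 control probe sets were left out of the tests. Where several kept probe sets named the same gene alone, the one with the highest mean over all arrays stood for it, and probe sets without a single gene name were tested as features of their own. This left 10961 features. The number of arrays limits the precision.

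The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A difference is the selected mean minus the control mean, and fold and difference carry the moderated standard error of limma. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 27 lists with at least 5 measured members, and beside it with the estimated correlation and with fry, which tests whether the genes of a list move on balance one way. Members were also counted with limma's p adjusted over the list alone. A list score per line is the mean over members of the log2 value minus each gene's mean over the 10 arrays. Scores were compared in exact two-sided permutation tests over the 252 labelings of the lines. Places on chromosome arms were tested with Fisher's exact test, and neighbouring genes with 100000 shuffles within arms.

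The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The 28 lists held 674 entries, of which 27 matched no gene. A further 3 entries (tan, Act-r and Mlp) matched a gene other than the one meant and were left out, a choice made after the files were opened and before list results were computed. The lists were written from textbook knowledge, and some by name pattern, which placed the cuticle genes Acp1 and Acp65Aa among accessory gland genes. Lists can share entries, such as Pxn in the hemocyte and antioxidant lists and foxo and Thor in the other stress and insulin signalling lists. The phototransduction list follows what is known of the study itself. The rule for named genes asked for up to 12 genes per direction past the threshold with separate groups, filled to 6 per direction by the smallest unadjusted p, up to 4 members per list by the smallest p, and a fixed set of heat shock and phototransduction genes whatever their values. The flight muscle genes Act88F, fln, TpnC4 and Mlp60A, the hemocyte gene Col4a1, the larval fat body genes Fbp1 and Fbp2 and the neighbours Cp38 and CG13083 were named after their values were seen.

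The test was checked on simulated data for this comparison with 10961 genes, 200 of them changed. It recovered 73.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 12 false calls. The simulation left out differences shared by many genes, such as those seen along the first principal component. A simulated shift of 0.3 in a list of 25 genes was recovered by camera with the preset (adjusted p = 1.42e-16) and the estimated correlation (adjusted p = 3.00e-04), and 0 of 26 other lists were called. Genes were drawn independently of one another here, so the check cannot show how often camera calls lists of correlated genes by chance.

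Alternatives changed the filter (none, or log2 above 5), the normalization (quantile, or centring each array on its median), the pseudocount (16), the eBayes options (trend and robust), the weighting of arrays, the choice of probe set per gene, the threshold, the list test, the use of line number as a block, and left out each line in turn. Added after the data were seen were an exact permutation of list scores, the fits without line 1 of both groups and without 4 flight muscle genes, the arm and neighbour tests at an unadjusted p under 0.01, and lists without members whose mean was no higher than the brightest probe set of another organism. Other splits of the lines were drawn 100 times out of 126. RNA integrity was read from the 3' minus 5' log2 signal of fly control probe sets for actin, eIF-4a and GAPDH. Calculations outside R used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.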

Results

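Transcript levels were measured across the genome in whole adult females of the fruit fly Drosophila melanogaster from 10 laboratory lines. Of these, 5 lines had been selected for resistance to heat and 5 were unselected controls, and each line gave 1 RNA sample hybridised to 1 array. The lines of a group were independent of one another per the series design, so the spread between arrays is a spread between lines. The median intensity of an array lay between 41.9 and 48.3, and single values ranged from 0.830 to 32744. On the log2 scale every pair of arrays correlated at an r of 0.984 to 0.997 across probe sets, which are not independent replicates. Of the probe sets, 10961 features were bright enough to be compared, 9672 of them with a gene symbol. The number of arrays limits the precision, and the median standard error of a difference between the groups was 0.095 on the log2 scale.

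The first principal component carried 33.6% of the variance and set line 1 of both groups (scores of -24.7 and -23.2) apart from the other lines, which scored from -9.82 to 15.4. The same arrays had the highest excess of 3' over 5' signal on fly control transcripts, which grows as RNA is degraded or incompletely copied. It was 2.27 and 2.76 on the log2 scale in line 1 of the control and selected groups and at most 1.93 elsewhere. By group the excess was 1.92 ± 0.21 in the control lines and 1.85 ± 0.52 in the selected lines (SD, n = 5 each, two-sided exact permutation p = 0.802). The second component carried 25.3% of the variance, and every control line (-1.03 to 21.8) scored above every selected line (-17.1 to -2.84).

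**Figure D1:**
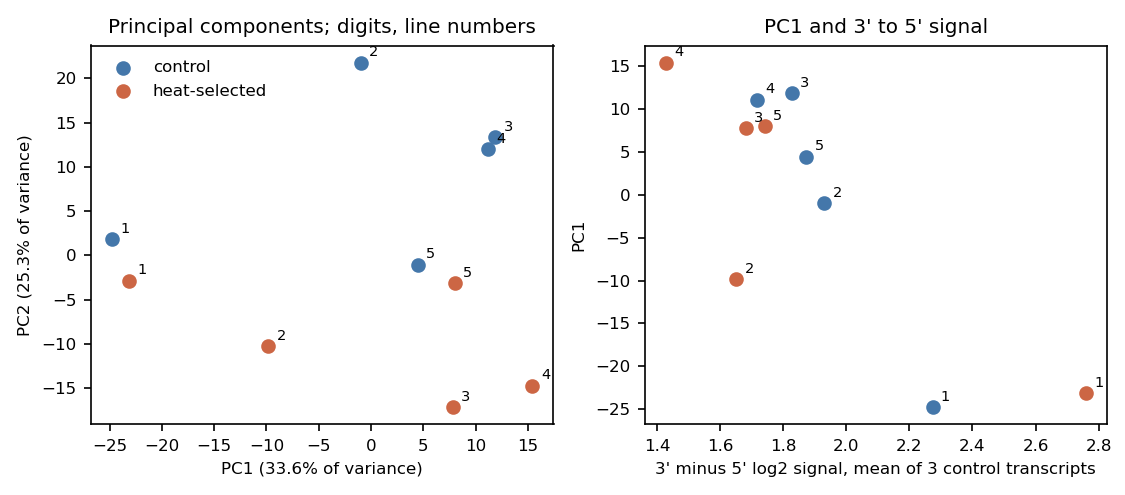
Left, scores of the 10 arrays on the first and second principal components, in arbitrary units, with the percent of variance on each axis. Right, the first component against the 3' minus 5' log2 signal averaged over 3 control transcripts. Points are lines, coloured by group and numbered; line 1 of both groups lies apart, at 2.27 and 2.76 on the signal axis.

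The main comparison asks which transcripts differ between flies of heat-selected and control lines. Transcripts of muscle proteins, of mitochondrial oxidative phosphorylation, of the phototransduction cascade of the eye and of the nervous system were higher as groups in the selected lines, and transcripts of yolk and eggshell proteins and of the germline were lower. The median log2 difference, selected minus control, was 0.80 over 24 muscle genes, 0.27 over 66 oxidative phosphorylation genes, 0.34 over 25 phototransduction genes and 0.22 over 26 neural genes. It was -0.54 over 20 yolk and eggshell genes and -0.11 over 30 germline genes. These 6 groups passed limma's camera test with a preset correlation of 0.01 between genes (adjusted p between 4.35e-21 for muscle and 8.64e-05 for the germline), and all 6 did so with the same direction when any 1 line was left out. None of the 6 passed with an estimated correlation between genes (adjusted p = 0.147 for each), with limma's fry (adjusted p of 0.0626 to 0.0760), or in an exact permutation test of the score of the list in each line (adjusted p = 0.119, and 0.150 for the germline). The smallest two-sided p that 5 lines against 5 can give is 0.00794, so a list could not pass the adjusted permutation test on its own. Of 27 lists tested, 14 passed camera with the preset correlation, 11 higher and 3 lower in the selected lines, and 0 passed with an estimated correlation.

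**Figure D2:**
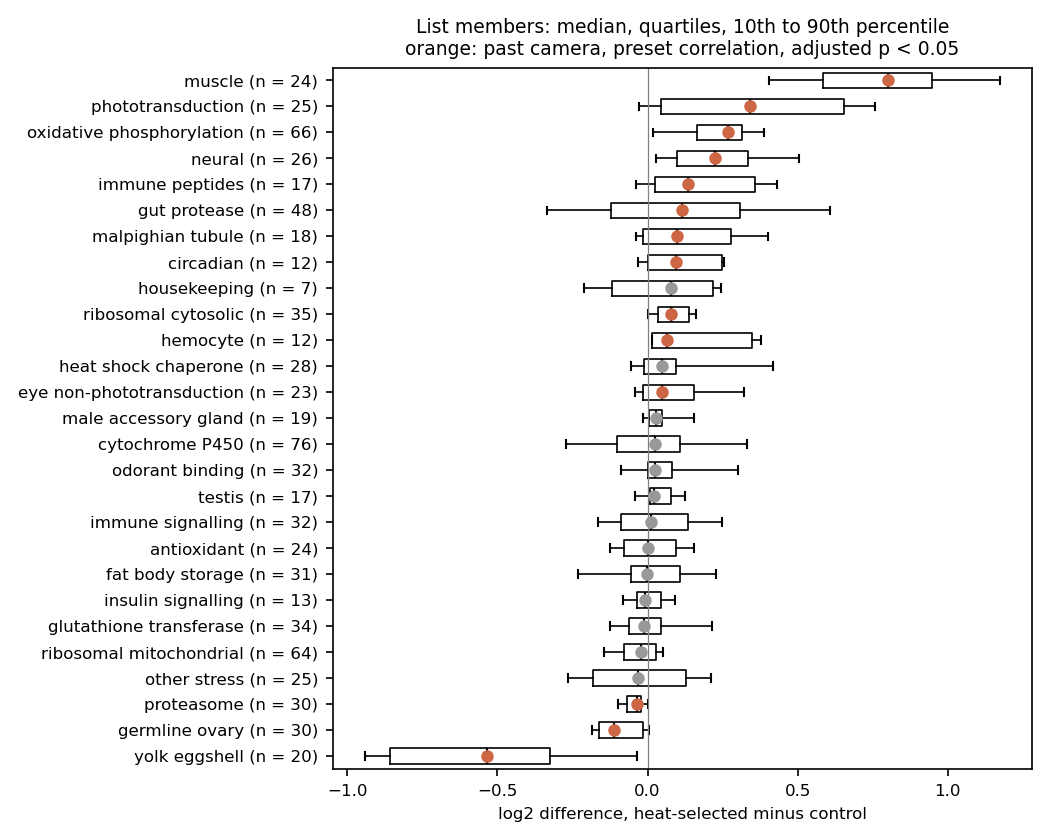
Log2 differences, heat-selected minus control, of the measured members of 27 gene lists (n, members). Points are medians, boxes quartiles and whiskers the outermost deciles of members; orange marks the 14 lists past camera with the preset correlation, from muscle (0.80) to yolk and eggshell (-0.54), none of which passed with an estimated one.

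Among muscle genes, 23 of 24 had a higher mean in the selected lines, and 20 rose when adjusted over the list alone, against 0 over all genes. Tropomyosin 2 (Tm2), which winds along thin filaments, rose from a log2 level of 7.41 ± 0.42 to 8.32 ± 0.27 (SD, n = 5 each). The giant elastic protein sls rose from 6.52 ± 0.42 to 7.31 ± 0.19 and the Z-disc protein Zasp66 from 9.66 ± 0.38 to 10.40 ± 0.16. The actin gene Act79B rose by 0.77 ± 0.19 (SE). The muscle score, the mean of the members with each gene centred over all arrays, was higher in 4 selected lines than in any control line. It lay between 0.66 and 0.71 in selected lines 2, 3 and 4, at 0.093 in line 5 and at -0.19 in line 1, whose RNA had the largest 3' excess. The control lines ran from -1.09 in line 2 to 0.033 in line 5. Of the flight muscle genes Act88F, fln, TpnC4 and Mlp60A, all 4 were lowest in line 2 among control lines and in line 1 among selected lines. The median without these 4 genes was 0.78 over 20 members, and over all members it was 0.66 without control line 2 and 0.80 without selected line 1. Oxidative phosphorylation moved beside muscle: 62 of 66 members had higher means and 29 were at an unadjusted p under 0.05, but 0 passed when adjusted over the list alone, where the smallest adjusted p from limma was 0.0797. Its leading members were the complex I subunit ND-39 (0.47 ± 0.13, SE) and the ATP synthase subunit ATPsynE (0.35 ± 0.093). The score of this list was higher in 3 selected lines than in any control line, and lower in selected line 1 (-0.085) than in control line 1 (0.089).

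**Figure D3:**
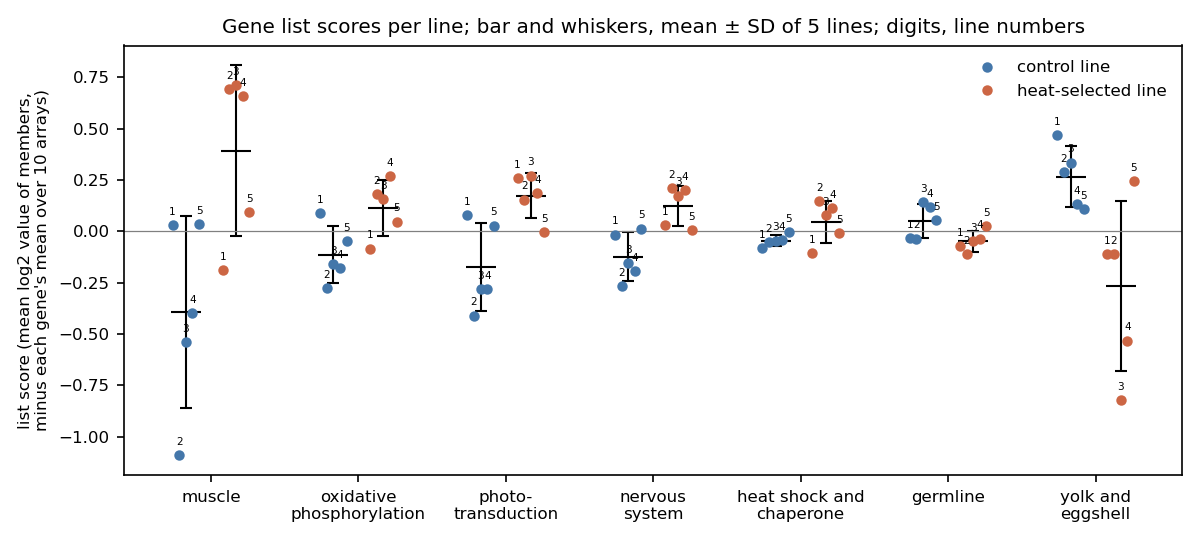
Scores of 7 gene lists in each line: the mean log2 value of the members after each gene's mean over the 10 arrays was removed. Points are lines, numbered and coloured by group, and bars show mean ± SD of 5 lines. Selected lines 2, 3 and 4 have muscle scores of 0.66 to 0.71, above all control lines.

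Phototransduction genes turn light absorbed by rhodopsin into the receptor current of the photoreceptor cell. Of 25 measured, 19 had higher means in the selected lines, 7 rose when adjusted over the list alone and 0 over all genes. The study is known to have reported this group from these same samples, so the count is not independent evidence of its direction. The arrestins, which shut off activated rhodopsin, rose from 9.58 ± 0.39 to 10.35 ± 0.23 for Arr1 and from 10.44 ± 0.41 to 11.13 ± 0.30 for Arr2 (SD, n = 5 each). The G protein subunit Gbeta76C rose by 0.75, the scaffold inaD by 0.76, the photoreceptor gene rtp by 0.83 and the light-activated channel trp by 0.64. The protein kinase C gene inaC differed by 0.56 ± 0.22 (SE) and did not pass. The genes ninaE and norpA had no measured probe set that names them alone. The score of the list ran from 0.15 to 0.27 in selected lines 1 to 4, above all control lines, and was -0.0040 in selected line 5, below control lines 1 (0.080) and 5 (0.028); control lines 2, 3 and 4 ran from -0.41 to -0.28. Of 23 other eye genes 15 had higher means, with a median of 0.047 and 0 past when adjusted over the list alone. Among them the photoreceptor adhesion gene chp differed by 0.69 ± 0.24 and the pigment transporter gene st by 0.50 ± 0.17 (SE). The mean levels of 9 were no higher than the 3.64 reached by probe sets of other organisms, and the median of the other 14 was 0.053. The score of the other eye list was above all control lines in 4 selected lines (exact permutation p = 0.0159, adjusted p = 0.119). The list passed camera (adjusted p = 0.0483) but not with an estimated correlation (adjusted p = 0.374), without its 9 dim members (adjusted p = 0.0865) or with quantile normalization (median 0.00074, adjusted p = 0.239). With 1 line left out it passed camera in 3 of 10 fits, and the median was -0.0020 without control line 1 and 0.0046 without selected line 4.

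Nervous system genes moved beside the phototransduction genes. Of 26 measured, 24 had higher means, and 4 rose when adjusted over the list alone. These were futsch (0.44), a microtubule-binding protein of axons, Ddc (0.73) and Vmat (0.50), which make and store monoamines, and the sodium pump subunit nrv3 (0.66). Among 12 circadian genes the photoreceptor cry rose by 0.41 when adjusted over the list alone. The median of that list was 0.093 (camera adjusted p = 0.0452, and adjusted p = 0.147 with an estimated correlation), and 0.061 without selected line 5.

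Yolk and eggshell genes were lower in the selected lines for 19 of 20 members, and 6 fell when adjusted over the list alone, against 0 over all genes. The chorion gene Cp19 fell from 13.50 ± 0.20 to 12.58 ± 0.54 and Cp16 from 11.60 ± 0.16 to 10.65 ± 0.64 (SD, n = 5 each). The chorion gene Cp36 fell by 0.47 and the yolk protein gene Yp3 fell by 0.34. Scores of this list were below all control lines in 4 selected lines, lowest in line 3 (-0.82). Selected line 5 scored 0.25, above control lines 4 (0.13) and 5 (0.11). Germline genes had lower means for 25 of 30 members and 0 passed when adjusted over the list alone. CycE, which drives entry into S phase, had the smallest p (-0.38 ± 0.093, SE, adjusted p = 0.0517 over the list alone from limma). Genes of male tissue, listed as a check on the samples, did not pass: the median was 0.026 over 19 accessory gland genes (adjusted p = 0.521) and 0.022 over 17 testis genes (adjusted p = 0.561). The accessory gland list was built by gene name and holds Acp1 and Acp65Aa, which encode cuticle proteins and differed by 1.88 ± 0.91 and 0.74 ± 0.70 (SE).

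Heat shock and chaperone genes did not pass as a group. Of 28 measured, 19 had higher and 9 lower means in the selected lines, 0 passed when adjusted over the list alone, and the median difference was 0.047 (camera adjusted p = 0.188, and adjusted p = 0.751 with an estimated correlation). Leaving out control line 1 turned the median to -0.0075. The highest median over the 10 lines left out was 0.092, without selected line 1 (camera adjusted p = 0.0558). The score of the list was above all control lines in 3 selected lines and below them in 1 (exact permutation p = 0.111). The small heat shock protein gene l(2)efl differed by 0.67 ± 0.22 (SE, unadjusted p = 0.0112, higher than the control median in 5 selected lines). Hsp68 differed by 0.55 ± 0.35, Hsp26 by 0.095 ± 0.15, Hsp27 by -0.093 ± 0.092 and Hsf, the transcription factor of the heat shock response, by -0.041 ± 0.091. The Hsp70 copies, Hsp22, Hsp23 and Hsp83 had no measured probe set that names them alone. In a list of 25 other stress genes, 0 passed when adjusted over the list alone and the median was -0.032 (camera adjusted p = 0.829). The trehalose synthesis gene Tps1 led it, at 0.51 ± 0.14 (adjusted p = 0.0832 over the list alone from limma).

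A further 6 lists passed camera and did not pass with an estimated correlation. Genes of the cytosolic ribosome had a median of 0.078 over 35 members (camera adjusted p = 8.51e-05, and 0.374 with an estimated correlation), with 0 past when adjusted over the list alone. Proteasome genes had a median of -0.036 over 30 members, 26 of them lower (adjusted p = 0.0342, and 0.475 estimated). Antimicrobial peptide genes had a median of 0.13 over 17 members (adjusted p = 0.0488, and 0.431 estimated). Among them Def, a defensin, rose from 5.62 ± 0.29 to 6.50 ± 0.38 when adjusted over the list alone, while Mtk, the gene of the peptide metchnikowin, differed by -1.66 ± 0.73 (SE) without passing. Digestive enzymes had a median of 0.12 over 48 members (adjusted p = 0.0428, and 0.751 estimated): the maltases Mal-B2 (0.71) and Mal-A8 (0.74) rose and the serine protease Jon25Bii fell by 1.27 when adjusted over the list alone. Hemocyte genes had a median of 0.063 over 12 members (adjusted p = 0.0379, and 0.147 estimated). Within it Hml (0.48), Ppn (0.64), Pxn (0.29) and Col4a1 (0.34) rose and the GATA factor srp fell by 0.64 when adjusted over the list alone. Malpighian tubule genes had a median of 0.097 over 18 members (adjusted p = 0.0342, and 0.147 estimated), and the potassium channel Irk3 rose by 0.64 when adjusted over the list alone. Leaving out 1 line moved some of these medians by over 1.5 times: digestive enzymes to 0.21, 0.067 and 0.058 without control lines 1, 3 and 4, hemocyte genes to 0.12 without control line 1 and 0.10 without selected line 4, proteasome genes to -0.023 without control line 2 and -0.054 without selected line 4, and ribosomal and Malpighian tubule genes to 0.12 and 0.15 without selected line 2. Without members no brighter than probe sets of other organisms, the calls of antimicrobial peptide genes (median 0.26 over 13), Malpighian tubule genes (0.042 over 16) and circadian genes (0.13 over 11) ended, each at an adjusted p of 0.0584 from camera. With each of the 10 lines left out in turn, the ribosomal call held in 10 fits, the proteasome call in 8, the Malpighian tubule call in 6, the digestive enzyme, hemocyte and circadian calls in 5 each and the antimicrobial peptide call in 4. Of all 14 calls, 7 ended without control line 2 and 7 without selected line 1, 6 without control line 3, 4 without selected line 2, and 1 or 2 without any other line.

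The remaining lists did not pass camera. Medians were -0.022 over 64 mitochondrial ribosomal genes (adjusted p = 0.103), 0.024 over 32 odorant-binding protein genes (adjusted p = 0.185), 0.026 over 76 cytochrome P450 genes (adjusted p = 0.879), -0.012 over 34 glutathione transferase genes (adjusted p = 0.879), 0.00089 over 24 antioxidant genes (adjusted p = 0.879) and 0.011 over 32 immune signalling genes (adjusted p = 0.959). They were -0.0087 over 13 insulin signalling genes (adjusted p = 0.829), -0.00040 over 31 fat body and storage genes (adjusted p = 0.964) and 0.078 over 7 housekeeping genes (adjusted p = 0.959). The mean of the glutathione transferases was 0.013, opposite in sign to their median and to camera, and camera ranked the immune signalling and antioxidant genes lower although both their mean and median lay above 0. When adjusted over the list alone, the odorant-binding protein genes Obp44a (0.68) and Obp18a (0.56) and the fatty acid synthase gene FASN2 (0.89) rose, the storage protein gene Lsp2 fell by 3.49, and the general transcription factor gene Tbp fell by 0.26. The detoxification gene Cyp4e3 differed by -1.48 ± 0.42 (SE) and Cyp6g2 by 0.47 ± 0.10 without passing. Both group means of Cyp6g2 (3.10 control, 3.57 selected) lay below the 3.64 of the brightest probe set of another organism. The turandot stress list had too few measured members to be tested.

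At the level of single genes, limma called 0 features at an adjusted p under 0.05 or under 0.10, and the smallest adjusted p was 0.232. At an unadjusted p under 0.05 there were 1043 features, 608 higher and 435 lower, where 548 would be expected with no difference. At an unadjusted p under 0.01 there were 304, 217 higher and 87 lower, against 110 expected. The groups did not overlap for 174 features (1.59%, where chance gives 0.794%). The storage protein gene Lsp2, best known from larval serum, had the largest difference of the named genes, from a log2 level of 9.68 ± 0.87 in the control lines to 6.20 ± 1.15 in the selected lines (SD, n = 5 each). With the smallest p among lower genes stood also CG18088 (-1.45), the eggshell gene Femcoat (-1.43), CG4066 (-1.02), CG13084 (-0.96) and Acer (-0.31), a relative of angiotensin-converting enzyme. Among higher genes stood CG1648, from 9.49 ± 0.58 to 11.16 ± 0.46, with CG42319 (1.14), fau (0.92), a gene named for its induction by anoxia, the maltase Mal-B2 (0.71), CG5023 (0.67) and the ribosome assembly factor LTV1 (0.47). The 12 genes had separate groups and adjusted p of 0.232 to 0.234 over all features from limma, so none is called changed over all genes. The 304 features became 627 without line 1 of both groups, 532 without control line 1, 195 without control line 3 and 184 without control line 4.

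**Figure D4:**
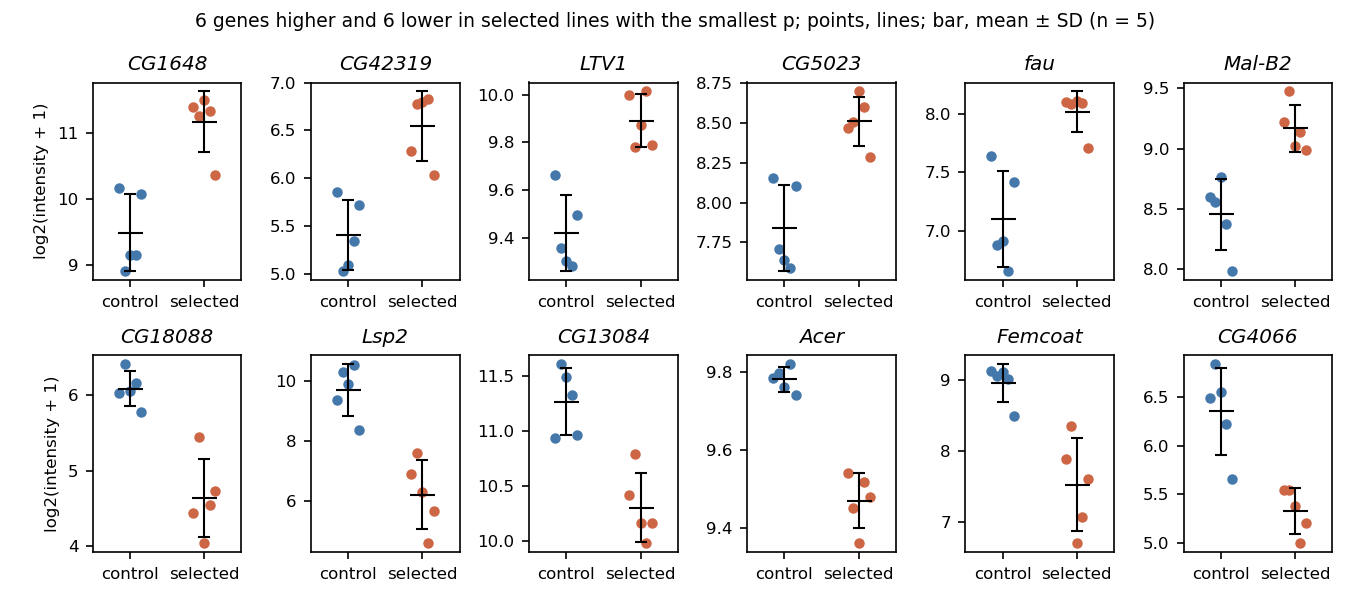
Log2(intensity + 1) of the 6 genes higher and the 6 lower in the selected lines with the smallest p. Points are lines, bars the mean ± SD of 5 lines, and each axis has its own range. The groups do not overlap for any of the 12 genes; the means of Lsp2 are 9.68 and 6.20.

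Lines that were selected apart can differ in linked stretches of the genome, so the places of differing genes were compared by chromosome arm. The planned test on genes past an adjusted p of 0.05 or 0.10 had 0 genes to place, and genes at an unadjusted p under 0.01 were used in its place. Among 9582 located genes, 263 met that level. No arm passed Fisher's exact test after adjustment. The highest share of genes with higher levels lay on 3R, with 61 of 2422 genes (2.52%, against 1.95% of all located genes, odds ratio 1.44, two-sided exact p = 0.0218, adjusted p = 0.109 over 5 arms). Adjacent measured genes both met the level in 13 pairs of neighbours, against a mean of 7.15 when genes were shuffled within arms (one-sided permutation p = 0.0276). The pairs included the chorion genes Cp36 with Cp38 on the X and Cp19 with Cp16 on 3L, the proteases Jon25Bii and Jon25Bi on 2L, and CG13084 with CG13083 on 2L. Without neighbours of a shared list, 10 pairs were left against a mean of 7.06 (p = 0.171 in the same permutation test), which was within what shuffling gave.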

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

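The 100 splits of the lines for genes at an unadjusted p under 0.01, for the number of lists and for list medians were planned before their results were seen. The count of splits at the adjusted threshold and the tests of RNA quality, ovary share, head share and larval fat body were chosen after the values they use had been seen, and the criterion for head share was revised after its result.

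Chance could not be excluded for the single genes. A split of the 10 lines into 5 and 5 gave as many genes at an unadjusted p under 0.01 as the real split (304) in 9 of 100 splits, the real one included. The other splits had a median of 33 and a highest count of 707. The 3 splits with the most genes put lines 1 and 2 of both groups on one side, which points to a structure of the samples that is not the selection. The splits were not balanced over these lines, so this structure is part of what they count as chance. As many as 14 lists past camera came from 12 of 100 splits, with a median of 7 and a highest count of 17 in the other splits. Passing camera with the preset correlation is therefore not particular to the real split. For single lists, a median as far from 0 as the real one came from 1 split for muscle (0.80, highest other 0.72), 1 for neural genes (0.22 and 0.22), 1 for yolk and eggshell (0.54 and 0.52 as sizes) and 3 for oxidative phosphorylation (0.27 and 0.34). Chance is excluded at 0.05 for each of these 4 lists taken alone, but not once the 27 lists tested are allowed for, since the exact permutation of list scores gave an adjusted p of 0.119 for each. With a smallest possible p of 0.00794, a list could not pass this adjustment on its own, whatever the size of its shift. For phototransduction 4 splits gave as much (0.34, highest other 0.38), which cannot exclude chance, because the study is known to have reported this group from these same samples. Chance is not excluded for the germline (5 splits, 0.11 and 0.15) or for heat shock and chaperone genes (35 splits, 0.047 and 0.14). At an adjusted p under 0.05 the real count was 0, which all 100 splits reach whatever the data, so that count bears on nothing; the highest other split gave 16.

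Muscle genes higher together with eggshell genes lower is the pattern with the largest list shifts. RNA quality as its account could not be decided. The mean 3' minus 5' signal was close in control and selected lines (1.92 ± 0.21 and 1.85 ± 0.52, SD, exact permutation p = 0.802), but selected line 1 (2.76) raised the selected mean. Selected lines 2, 3 and 4, with the highest muscle scores, had signals of 1.65, 1.68 and 1.43, where control lines ran from 1.72 to 2.27. Going the other way, control line 1 (2.27) had a muscle score of 0.031, above control lines 2, 3 and 4. With group means this close, the signal as a covariate could hardly move the median muscle difference, 0.79 with it and 0.80 without. The list stayed past camera with the preset correlation (with an estimated correlation it did not pass, at an adjusted p of 0.185 with the covariate and 0.147 without). Effects of RNA quality, across the groups or in single lines, are not excluded by this. A smaller share of ovary RNA, which would raise all other tissues alike, is argued against as the whole account, though only at an unadjusted p: the muscle score minus the mean score of the gut, fat body, Malpighian tubule and hemocyte lists was 0.71 higher in the selected lines (-0.36 ± 0.39 against 0.36 ± 0.45, SD, exact permutation p = 0.0397), and the muscle minus the neural score 0.54 higher (exact permutation p = 0.0397), while phototransduction minus muscle differed by -0.44 (exact permutation p = 0.0794). Contrasts here and for the next pattern were read at their own unadjusted p, and none of the 7 between lists passed adjustment (smallest adjusted p = 0.0778). With a smallest possible p of 0.00794, a contrast among 7 could not pass adjustment on its own. A lower ovary share stays open, with or without a change in muscle itself. The age or egg-laying state of the flies was not tested, and an effect of selection stays open as a hypothesis.

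Phototransduction genes higher is the second pattern. RNA quality could not be decided as its account either, since selected lines 2, 3 and 4 had a lower 3' minus 5' signal than any control line. Going the other way, selected line 1, with the highest signal (2.76), had a phototransduction score of 0.26, above all control lines. The median was 0.36 with the covariate and 0.34 without, which the close group means of the signal largely fixed. The list was past camera with the preset correlation (with an estimated one it did not pass, at an adjusted p of 0.185 with the covariate and 0.147 without). A larger share of head RNA would raise neural and other eye genes alike, and the group differences of neural scores (0.18, exact permutation p = 0.0556) and phototransduction scores (0.27, exact permutation p = 0.0159) over the same 4 tissue lists go the way it needs, as a change in the eye and nervous system would. It cannot be told apart from a change in the photoreceptors, because phototransduction minus neural scores differed by 0.098 (exact permutation p = 0.190) and phototransduction minus other eye genes, 9 of the 23 near the floor, by 0.25 (exact permutation p = 0.0556), neither under 0.05. Both readings, and selection acting on vision genes, stay open as hypotheses.

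The lower Lsp2 level is the third pattern. Larval fat body that persists in young adults may carry Lsp2 RNA, which would make the control flies younger or less far in its removal. Other larval fat body genes did not decide it: Fbp1 differed by 0.13 ± 0.16 and Fbp2 by -0.057 ± 0.065 (SE), but in the control lines Fbp2 (3.57) lay below the 3.64 of the brightest probe set from another organism and Fbp1 (4.05) 0.40 above it, so that little of a fall like the -3.49 of Lsp2 could have been seen. The rule, set with these values in view, let a gene decide only at a level more than 1 above that probe set, which neither reached. The explanation therefore cannot be told apart from a change in adult expression.

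A single line lay far from the other 4 of its group in 17 of 302 groups of values tested, about the 1 in 20 that chance gives, by Dixon's test, the gap to the nearest line over the range. For list scores these were glutathione transferases in control line 1 (0.26), cytosolic ribosomal genes in selected line 2 (-0.10) and mitochondrial ribosomal genes in selected line 1 (0.082). In selected line 5 the log2 values of CG1648 (10.35), fau (7.71), Arr1 (9.93) and Act79B (10.24) lay below the other selected lines, and that of pum (10.01) above them. Selected line 3 had Acp1 at 11.21, where the other selected lines ran from 5.09 to 6.86, and Acp65Aa at 7.55, where they ran from 3.31 to 4.42, both cuticle genes, and a low Jon25Bi (9.23). The others were Femcoat in control line 5 (8.49), Hsf (8.86) and GstO1 (8.54) in selected line 4, lectin-46Ca in selected line 1 (4.39), RpL23 in selected line 2 (12.07) and Prosbeta3 in control line 2 (11.08).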

How the results depend on the processing

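The exact permutation of list scores, the fits without line 1 of both groups and without 4 flight muscle genes, the lists without dim members, and the arm and neighbour tests at an unadjusted p under 0.01 were chosen after seeing the data, and the arm test at the planned thresholds was not run, because 0 genes passed them. Levels near those of probe sets from other organisms set a floor. Causes were not tested except where stated. Over the 12 alternatives other than leaving out a line that refit single genes, all 1477 values of 124 named genes kept their direction. These are refits of the same 10 arrays, and most of the genes were named for a small p, so few could be expected to turn. Features past the adjusted threshold numbered 7 (3 higher, 4 lower) with array weights and 0 to 3 with a line left out (3 without control line 5, and CG18088 alone without selected line 2), against 0 as reported, and 304 at an unadjusted p under 0.01. Those 304 became 742 with array weights, 627 without line 1 of both groups, and 184 to 532 with a line left out. The same-numbered lines of the groups had deviations that correlated at 0.55, 0.21, 0.20, 0.35 and 0.027. The numbers were taken as pairing the lines only if every pair exceeded 0.1, which 4 of 5 did. Of the 10 lines, 5 correlated best with the line of their own number. Between the groups, deviations correlated positively among lines 1 and 2 (0.13 to 0.55) and among lines 3 to 5 (0.027 to 0.43). Those between these sets were all negative (-0.46 to -0.058). A structure by line number was thus shared by the groups, of unknown source, and the main fit without a block left it in the spread between lines. A link between some same-numbered lines is left open. With the line number as a replicate block 2 genes passed (1 higher, 1 lower), 468 lay at an unadjusted p under 0.01 and 10 lists passed. The 14 lists past camera became 9 with the most variable probe set per gene and 10 without members no brighter than probe sets of other organisms. Quantile normalization left 10, ending the other eye, circadian, proteasome and hemocyte calls. Array weights left 10, ending the other eye, antimicrobial peptide, proteasome and hemocyte calls. Pseudocount 16 and every probe set left 11 each, the stricter filter 12 and no filter 13. With a line left out 7 to 13 passed (7 without control line 2, 8 without selected line 1, 9 without control line 3), and 13 without line 1 of both groups. The count was 0 with an estimated correlation, with fry and with the exact permutation of scores, which allow for correlated genes. These 3 tests use the same differences, so the medians of 0.80 (muscle), 0.27 (oxidative phosphorylation), 0.34 (phototransduction), 0.22 (neural), -0.54 (yolk and eggshell) and -0.11 (germline) stood while their calls ended. With a line left out these medians ran over 0.66 to 0.92, 0.20 to 0.33, 0.27 to 0.42, 0.18 to 0.27, -0.65 to -0.42 and -0.14 to -0.078. The phototransduction median depended more on the filter and the probe sets, at 0.11 with every probe set and 0.24 without the filter. It was 0.25 with pseudocount 16 and 0.56 with the stricter filter. Under the same settings, in that order, the neural median was 0.15, 0.17, 0.14 and 0.36. Medians near 0 changed sign under some settings. Antioxidant genes went to -0.0095 without the filter, -0.023 with quantile normalization, -0.0063 with centred arrays, -0.023 with every probe set and -0.0049 without line 1 of both groups. Fat body genes went to 0.0058 without dim members. With the stricter filter immune signalling went to -0.024 and insulin signalling to 0.0053. With quantile normalization the medians were -0.0040 for odorant-binding proteins, -0.0064 for accessory gland, -0.0090 for testis, -0.014 for cytochrome P450 and 0.0027 for fat body genes. With array weights they were 0.014 for other stress, 0.011 for glutathione transferase, 0.012 for fat body, 0.0061 for insulin signalling and 0.0033 for mitochondrial ribosomal genes. Without line 1 of both groups they were 0.017 for other stress, -7.1e-05 for odorant-binding proteins, -0.0029 for accessory gland, -0.0074 for testis, 0.012 for glutathione transferase, 0.0039 for fat body, 0.021 for insulin signalling and 0.0030 for mitochondrial ribosomal genes. Leaving out single lines gave ranges of -0.0075 to 0.092 for heat shock and chaperone, -0.0020 to 0.053 for other eye, -0.015 to 0.053 for odorant-binding, -0.034 to 0.070 for accessory gland, -0.040 to 0.069 for testis, -0.0062 to 0.042 for cytochrome P450, -0.016 to 0.041 for antioxidant, -0.0070 to 0.031 for fat body, -0.041 to 0.017 for mitochondrial ribosomal, -0.043 to 0.0051 for glutathione transferase, -0.021 to 0.045 for immune signalling, -0.063 to 0.059 for insulin signalling and -0.073 to 0.017 for other stress genes. The mitochondrial ribosomal list then passed camera in 4 of 10 fits. Of single genes, Hsf ran from -0.10 to 0.012, EbpIII from -5.8e-05 to 0.27 and Acp65Aa from -0.023 to 1.04.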

Other observations

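Glycolytic and storage genes were measured beside the mitochondrial ones. In the housekeeping list the aldolase gene Ald1 differed by 0.31 ± 0.16 and Gapdh1 by 0.24 ± 0.15 (SE), each higher than the control median in 4 selected lines and none past when adjusted over the list alone. In the fat body list the lipase gene bmm (-0.27 ± 0.078) and the phosphatidate phosphatase gene Lpin (0.24 ± 0.089) did not pass when adjusted over the list alone. The malic enzyme gene Men (-0.33 ± 0.10) and the catalase gene Cat (0.32 ± 0.10) led the antioxidant list in opposite directions without passing, and the insulin-like peptide gene Ilp7 differed by -0.38 ± 0.11. The immune regulators Fadd (-0.48 ± 0.16) and PGRP-SB1 (-0.66 ± 0.23) led the immune signalling list without passing.

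Across the 10 lines the first principal component correlated with the 3' minus 5' signal at a Pearson's r of -0.81 (permutation p = 0.00566) and a Spearman's rho of -0.62 (permutation p = 0.0599), 1 relation tested in these 2 ways. Without the 2 lines farthest from the median signal, both of them line 1, r was -0.32, so the relation rests on line 1 of the groups.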
